A study of Caenorhabditis elegans with 2 samples.

How the data were processed

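The samples were 2 biological replicates of whole L4 larvae of *C. elegans* strain OP342, immunoprecipitated for eGFP-tagged SKN-1 and sequenced. The labels number them as biological replicates 1 and 2 of 1 group. For each of 2 genome builds, ce10 and ce11, a list of regions per replicate, a list from the pooled replicates and a thresholded list were used, 8 lists in all.

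The lists are in narrowPeak form and were made by the authors. Per the labels' file listing, each replicate's list and the pooled list hold peaks together with background regions, made from alignments and a control alignment as input for thresholding on the irreproducible discovery rate, and the thresholded list holds the peaks that passed. The peak caller, the aligner and the rate used as threshold are not given in the sources used here, and the control alignment is not used here. The signal value of each region (column 7) is the deposited value of the authors' caller; its scale is not stated, and it was used to rank and describe regions within a list. The deposited −log10 q-value (column 9) stopped at a ceiling in each list, and all 97 thresholded ce11 peaks had the same value, so it was not used for ranking. The deposited summit offset (column 10) was the middle of the region in nearly all rows. Each replicate's list holds exactly 30000 regions, whatever the strength of the weakest, so a region's presence in them does not mark it as bound. Region width was fixed within each replicate's list and the same in all but 4 regions of the pooled ce11 list, with a median of 240 bp in replicate 1, 396 bp in replicate 2 and 390 bp in the pooled ce11 list, so the replicates' lists differ in resolution. The 97 thresholded ce11 peaks were checked to be the 97 strongest regions of the pooled list, with signal values of at least 29.0, so the threshold acted as a single limit on pooled signal. The lists hold no read counts, and the depth of each sample and of the control is unknown.

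Coordinates are given from 1, on ce11. The ce11 lists were annotated with Ensembl release 115 genes and the WBcel235 sequence, which is the same assembly as ce11. No coordinates were converted between builds, and ce10 lists were used for counts and overlaps within ce10 and for the share of peaks per chromosome. The promoter window ran from 1000 bp upstream to 500 bp downstream of the outermost annotated start of each of 19973 protein-coding genes. A gene was counted as having a peak when a summit lay in its window, so a peak between neighbouring genes counts for both.

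Replicates were compared by the overlap, by at least 1 bp, of the 1000 strongest regions of each. Chance overlap came from 1000 random placements of replicate 2's regions on the same chromosomes (100 placements for 5000 regions). Peaks were compared with the 14884 weakest regions of the pooled list for promoter location and gene features. For the SKN-1 site WWTRTCAT they were compared with windows centred 1000 bp to each side. Tests against these flanks, those of hexamers included, treated windows as independent and did not pair a peak with its own flanks. Shares were tested with two-sided Fisher's exact tests and chromosome shares with two-sided exact binomial tests, at a threshold of 0.05. Intervals are Clopper-Pearson at 95%; for a count of 0, 3 counts of the total are given as the share still allowed, beside the exact upper limit. Families of tests were adjusted by the method of Benjamini and Hochberg. Because there is 1 group, no test compares conditions, and p-values describe regions or genes of these samples, not worms.

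Gene lists fixed before the data were examined numbered 27, and 2 of 185 listed symbols had no match in the annotation. They covered ribosomal proteins, mitochondrial ribosomal proteins, tRNA synthetases, the proteasome, the respiratory chain, chaperones, the unfolded protein response of the endoplasmic reticulum, lysosome and autophagy, histones, lipid metabolism and stress signalling. Gene families were detoxification and redox genes, glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450s, short-chain dehydrogenases, ABC transporters, nuclear receptors, collagens, insulin-like peptides, chemoreceptors and endoderm factors. Marker lists for intestine, muscle, neurons, hypodermis and germ line completed the set. The genes named are those of the 15 strongest thresholded peaks (the promoter-window genes or else the nearest protein-coding gene), up to 20 genes by signal of the fixed lists other than the nuclear receptor, collagen and chemoreceptor families with a peak in their window, and *skn-1*, *gst-4* and *gcs-1* in any case; an item that this rule takes is not reported here.

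The tests of replicate overlap, the site, gene lists and hexamers were tested on simulated data; the other shares and the percentiles were not. Of 60 random lists of 1000 regions, 4 passed the threshold for replicate overlap, and 100 planted shared regions gave 100.5 overlaps more than chance. For the site, 0 of 20 simulated sets of 97 peaks were called higher without planted sites, and 20 of 20 were called with sites planted in 20 peaks. For gene lists, 2 lists were called over 20 sets of random promoters, and 20 of 20 sets with 7 planted ribosomal protein genes were called. For hexamers in 97 windows, 0 were called over 10 random sets, and GAGAGA planted in 40 windows was called in 10 of 10, with 8 other hexamers over those sets. The random windows were not matched to the GC content of the summit windows. The 0 calls therefore do not cover hexamers called through a difference in base composition. Settings varied were the number of strongest regions, the overlap rule, the promoter window, the site and its window, the background, the peak threshold, the genome build and each replicate left out. Analyses used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.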

Results

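Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to find where an eGFP-tagged copy of SKN-1 sat on the genome of *Caenorhabditis elegans* at the L4 larval stage. SKN-1 is a transcription factor related to the mammalian Nrf proteins, known for activating detoxification genes and for specifying endoderm in the embryo. Whole worms of strain OP342, in which an integrated transgene supplies the tagged protein in an *unc-119* mutant background, were sampled as 1 group of 2 biological replicates of mixed sex. No untagged or mock-precipitated worms are among the 2 samples. The comparisons below are therefore between the replicates, between strong and weak regions, between peaks and their flanks, and between peaks and lists of genes. On the ce11 assembly the authors' list after thresholding on reproducibility held 97 peaks. The relaxed list from the pooled replicates held 29768 regions, and the relaxed list of each replicate held 30000. Read depth is unknown, because the lists give no read counts. Intervals given for shares are exact 95% binomial intervals and cover counting error over regions or genes.

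Promoters of cytosolic ribosomal protein genes led the list of peaks. Of the 10 strongest peaks, 6 had their summit in the promoter window of such a gene, defined as 1000 bp upstream to 500 bp downstream of the annotated start. The strongest peak of all (chromosome III, 3867488 to 3867656, ce11) lay in the intergenic stretch 290 bp upstream of *rpl-3* (WBGene00004414), with a pooled signal value of 80.4. Signal values are the authors' own, are given without replicate error because they come from the pooled list, and rank regions within that list only. The next was centred 309 bp upstream of *rpl-20* and 153 bp upstream of its neighbour *Y17G9B.5* (chromosome IV, 4750001 to 4750127), with a signal of 73.5. Peaks at *rps-1* (signal 62.2), *rpl-35* (60.2), *rpl-15* (52.9) and *rpl-12* (49.1) followed, with summits 265, 459, 364 and 36 bp upstream of the gene starts. The windows of *ifet-1*, a translational repressor, *K11H12.8* and *lin-54*, a subunit of the DREAM repressor complex, shared the summits at *rps-1*, *rpl-15* and *rpl-12*.

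Other genes among the 15 strongest peaks had mixed functions. The summit 60 bp upstream of *iff-2*, which encodes the translation factor eIF5A, had a signal of 60.2 and also lay in the window of *F54C9.14*. The peak shared by *tasp-1*, a threonine aspartase gene, and *K01G5.10* (chromosome III, 10759168 to 10759292) had a signal of 66.6. A peak 5 bp downstream of the start of *atp-1*, encoding an ATP synthase subunit, fell in its 5′ UTR, had a signal of 48.6 and was shared with *mcrs-1*. The peak 315 bp upstream of *cox-5A*, encoding a cytochrome c oxidase subunit, had a signal of 47.6. A further 4 of the 15 had no start within the window. Their nearest protein-coding starts were those of *W02H3.3* (3983 bp away), *epg-9* (1064 bp, with the summit in an intron), *F20B6.9* (1809 bp) and *K02D3.1* (6001 bp), and 3 of these 4 peaks lay on chromosome X.

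**Figure D1:**
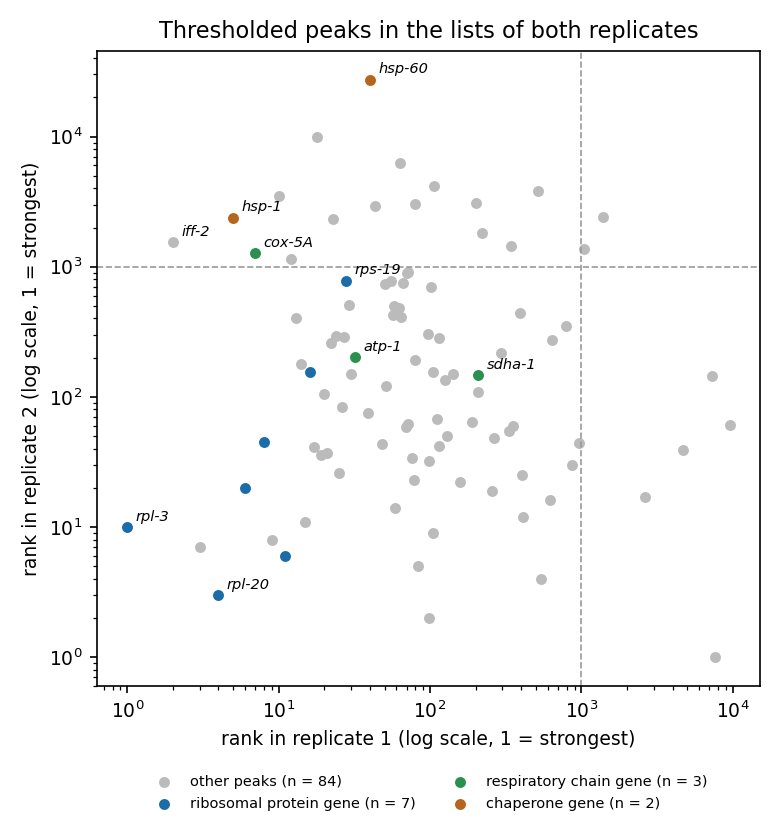
Rank of each thresholded ce11 peak by signal value in replicate 1 (x axis, log scale) and in replicate 2 (y axis, log scale), for the 96 peaks that overlapped a region in both lists; each point is a peak, coloured by the gene list of its promoter genes, and dashed lines mark rank 1000. The ribosomal protein gene *rpl-3* ranked 1 and 10, while the chaperone gene *hsp-60* ranked 40 and 27401.

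Cytosolic ribosomal protein genes and respiratory chain genes were found in the promoter windows of the peaks more often than other protein-coding genes. Of 81 ribosomal protein genes, 7 held a summit (8.64%, 3.55 to 17%), against 0.300 expected (odds ratio 27.99, two-sided Fisher's exact p = 2.00e-08, adjusted p = 5.41e-07 over 27 lists). Over relaxed pooled regions of any strength, 68 of the 81 genes had a region against 33.8 expected (odds ratio 7.37, Fisher's exact test, adjusted p = 1.10e-13). The seventh member with a peak was *rps-19* (signal 39.0), with a summit 289 bp upstream of its start and 156 bp upstream of that of *hsr-9*. Of 40 respiratory chain genes, 3 held a summit (7.50%, 1.57 to 20.4%), namely *atp-1*, *cox-5A* and *sdha-1*, a succinate dehydrogenase subunit gene (signal 33.2), against 0.148 expected (odds ratio 22.7, two-sided Fisher's exact p = 0.000437, adjusted p = 0.00590). The respiratory chain list had 0 of 40 genes among the 97 strongest regions of replicate 2 alone, and 4 against 0.793 expected among its 1000 strongest (Fisher's exact test, adjusted p = 0.0535). It passed among the 1000 strongest regions of replicate 1 (7 genes, exact test, adjusted p = 0.000345) and of the pooled list (5 genes, exact test, adjusted p = 0.0159). It did not pass in pooled regions shared with both replicates (3 genes, exact test, adjusted p = 0.0947 for the 500 strongest and 0.147 for all 825). Over relaxed pooled regions of any strength, 25 of the 40 respiratory chain genes had a region against 16.7 expected (exact test, adjusted p = 0.0324). That setting was not particular to these lists. Chaperones (39 of 60 genes), lysosome and autophagy (24 of 33), the proteasome (21 of 31) and mitochondrial ribosomal proteins (39 of 66) also passed. Their adjusted p by the exact test ran from 0.00221 to 0.0214. Chemoreceptors (349 of 1276) and histones (14 of 72) were depleted there. The ribosomal protein list passed in the 97 strongest regions of replicate 2, with 6 of 81 genes (Fisher's exact test, adjusted p = 2.75e-06).

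Of the other lists, 3 had an unadjusted p under 0.05 and did not pass after adjustment. The lysosome and autophagy list had 2 of 33 genes with a peak, *lgg-2*, an Atg8 family gene (signal 29.4, summit in an intron 335 bp downstream of the start), and *vha-1*, a subunit gene of the vacuolar proton pump (signal 29.2); Fisher's exact p was 0.00664 and adjusted p 0.0597. The chaperone list had 2 of 60, the cytosolic Hsp70 gene *hsp-1* (signal 42.3, 370 bp upstream) and the mitochondrial chaperonin gene *hsp-60* (signal 29.5, 583 bp upstream), with Fisher's exact p = 0.0209 and adjusted p = 0.113. The *hsp-60* summit was nearer to the start of *Y22D7AL.10*, 230 bp upstream of it. Chemoreceptor genes had 0 of 1276 against 4.73 expected (Fisher's exact p = 0.0146, adjusted p = 0.0983), where 3 counts of the total, or a share of 0.235%, remain allowed (exact 95% upper limit 0.289%). Each of these 3 lists passed under some of 10 alternative settings, the lysosome and autophagy list under 5, chemoreceptors (depleted) under 4 and chaperones under 3. Among genes with 1 of the 1000 strongest regions of a replicate, chemoreceptors were depleted in replicate 1 (4 genes against 31.7 expected, Fisher's exact test, adjusted p = 7.85e-09) and in replicate 2 (5 against 25.3, exact test, adjusted p = 1.54e-05). The lysosome and autophagy list passed in replicate 1 (6 genes, exact test, adjusted p = 0.000770) and in replicate 2 (4 genes, exact test, adjusted p = 0.0356). Chaperones passed in replicate 1 (12 genes, exact test, adjusted p = 2.06e-07) and not in replicate 2 (4 genes, exact test, adjusted p = 0.168). Single genes with a peak were *his-37* of 72 histone genes (signal 42.5), *ins-39* of 39 insulin-like peptide genes (signal 39.3), and, outside the rule for named genes and named after its value was seen, *nhr-35* of 269 nuclear receptor genes (signal 29.0); Fisher's exact test gave adjusted p of 0.906, 0.607 and 1 for these lists. In the remaining 19 lists, which had 9 to 175 members each, 0 genes had a peak (Fisher's exact p = 1 for each). Of these 19, the list for the unfolded protein response of the endoplasmic reticulum passed among the 1000 strongest regions of replicate 1 (4 of 16 genes against 0.397 expected, exact test, adjusted p = 0.00243) and not of replicate 2 (1 gene, exact test, adjusted p = 0.779). The other 18 passed in neither replicate there. In the unfolded protein response list, a peak lay inside *xbp-1*, named here after its value was seen. Its summit was 525 bp downstream of the start and so outside the promoter window. The region of replicate 1 that overlapped this peak (rank 352) lay inside the window and counted for *xbp-1*.

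The detoxification genes for which SKN-1 is known did not carry any of the 97 peaks. The list of 30 detoxification and redox genes had 0 with a summit in the promoter window, against 0.111 expected (two-sided Fisher's exact p = 1). With so few genes expected by chance, the count of 0 still allows 3 counts of the total, a share of 10% of the list (exact 95% upper limit 11.6%). In the relaxed pooled list 15 of the 30 genes had a region of any strength in their window, against 12.5 expected (Fisher's exact p = 0.361). The highest-ranked was *gcs-1* (WBGene00001527), encoding the enzyme of the first step of glutathione synthesis, with a region at chromosome II, 9038775 to 9039164, 669 bp upstream of its start, at rank 3338 (signal 14.2). For the glutathione S-transferase gene *gst-4* (WBGene00001752), a widely used SKN-1 reporter, the region 587 bp upstream (chromosome IV, 10141443 to 10141832) ranked 25442 of 29768 with a signal of 7.60. Replicate 1 listed no region in the *gst-4* window, and replicate 2 had one at rank 19338.

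Peaks were concentrated upstream of genes and sparse in coding sequence. Of the 97 peaks, 52 had their summit in a promoter window (53.6%, 43.2 to 63.8%), compared with 4233 of the 14884 weakest regions of the pooled list (28.4%, 27.7 to 29.2%; odds ratio 2.91, two-sided Fisher's exact p = 3.48e-07). The 52 peaks touched 75 windows of 74 genes, since 22 peaks lay in the windows of at least 2 genes. In 69 of the 75 windows the summit was upstream of the start, with a median position of -320 bp. Only 5 peaks (5.15%) had a summit in a coding exon, against 30.01% of the weakest regions (odds ratio 0.127, Fisher's exact p = 1.93e-09, adjusted p = 5.79e-09 over 6 classes). Introns held 15 peaks (15.5% against 31.0%, Fisher's exact test, adjusted p = 0.00117). Stretches between protein-coding genes held 72 (74.2% against 33.7%, Fisher's exact test, adjusted p = 3.86e-15). The 5′ and 3′ UTRs held 4 peaks and 1 peak, with Fisher's exact adjusted p of 0.112 and 0.319, and other exons held 0.

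**Figure D2:**
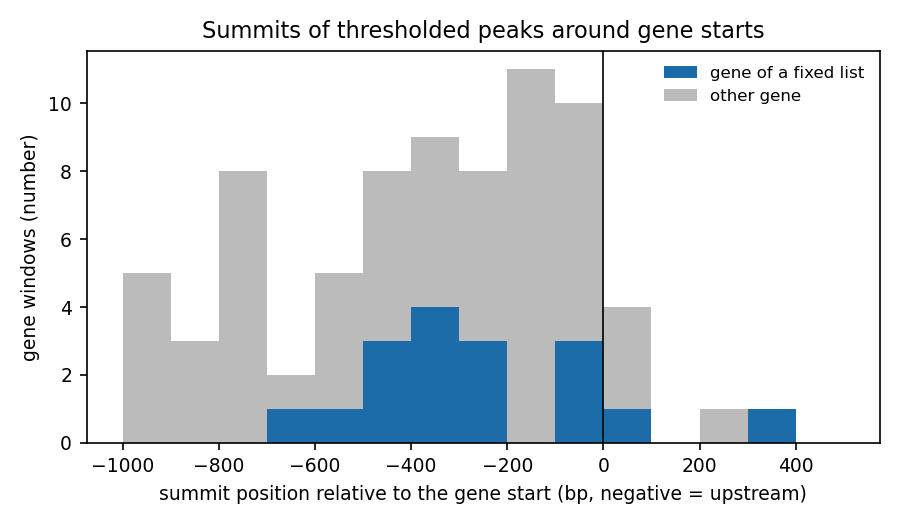
Number of promoter windows (y axis) by the position of the peak summit relative to the annotated gene start (x axis, bp in bins of 100, negative values upstream), for the 75 windows of 74 genes that held a summit. Blue bars are genes of the fixed lists and grey bars other genes; 69 of the 75 summits lay upstream.

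The SKN-1 binding site was no more frequent at the peaks than beside them. The site, WWTRTCAT on either strand, lay within 100 bp of the summit in 5 of 97 peaks (5.15%, 1.69 to 11.6%). It lay in 16 of 194 windows of the same length centred 1000 bp to each side (8.25%, 4.79 to 13.05%; odds ratio 0.605, two-sided Fisher's exact p = 0.472). The 5 peaks, named here after their values were seen, lay in the windows of *cdc-48.1*, *ins-39* and *nipi-3*, in an intron 1029 bp from the start of *aak-2*, and in an intron 4111 bp from the nearest start, that of *F38B7.2*. None of the 15 strongest peaks held the site. Across the pooled list the share of regions with the site ranged from 5.15% in the strongest 97 to 9.65% in ranks 20001 to 29768, where the flanking windows had 10.3%. In the same steps the promoter share fell from 53.6% to 28.4% and mean GC content from 46.5% to 37.0%. The site is rich in A and T. Neither the comparison with flanks nor that across ranks was corrected for base composition. Summits in nearly all regions were the middle of a region of fixed width, so a bound site could lie outside the window searched.

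**Figure D3:**
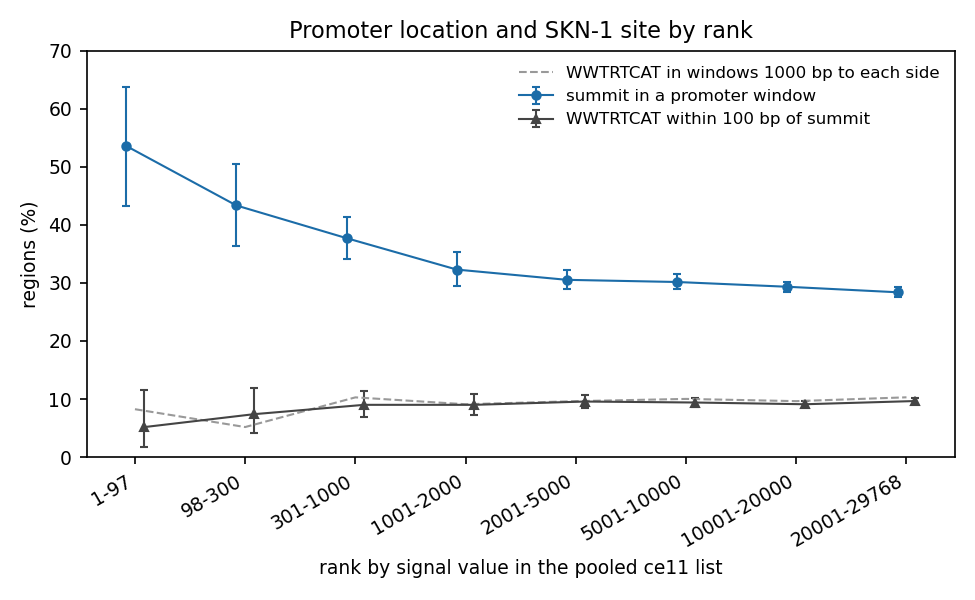
Share of regions (y axis, %) with the summit in a promoter window (circles) and with the site WWTRTCAT within 100 bp of the summit (triangles) by rank in the pooled ce11 list (x axis, rank bins); error bars are exact 95% binomial intervals and the dashed line is the share of windows 1000 bp to each side with the site. The promoter share was 53.6% in the first bin and 28.4% in the last, while the share with the site was 5.15% and 9.65%.

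Chromosome X carried more of the peaks than its length would give, by a margin close to the threshold. It held 26 of 97 peaks (26.8%, 18.3 to 36.8%), while it makes up 17.7% of the nuclear genome (two-sided exact binomial p = 0.0232, adjusted p = 0.0464 over 6 chromosomes). Chromosome III held 22 (22.7% against 13.7% of length), and chromosome V held 10 (10.3% against 20.9%), each with exact binomial adjusted p = 0.0464. In the ce10 list of 110 peaks, chromosome III held 21 and chromosome V 10. Tests under other settings are given for X only. Chromosomes I, II and IV held 12, 12 and 15 peaks, with exact binomial adjusted p of 0.685, 0.685 and 0.689. On X, 10 of the 26 summits lay in promoter windows (38.5%), against 42 of 71 on the autosomes (59.2%; odds ratio 0.432, Fisher's exact p = 0.107). Among the 48 strongest peaks the X share was 25% and did not pass the test (exact binomial p = 0.186). With adjustment over 6 chromosomes the excess on X also failed in the list of either replicate alone (exact binomial adjusted p = 0.0936 without replicate 1 and 0.135 without replicate 2).

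**Figure D4:**
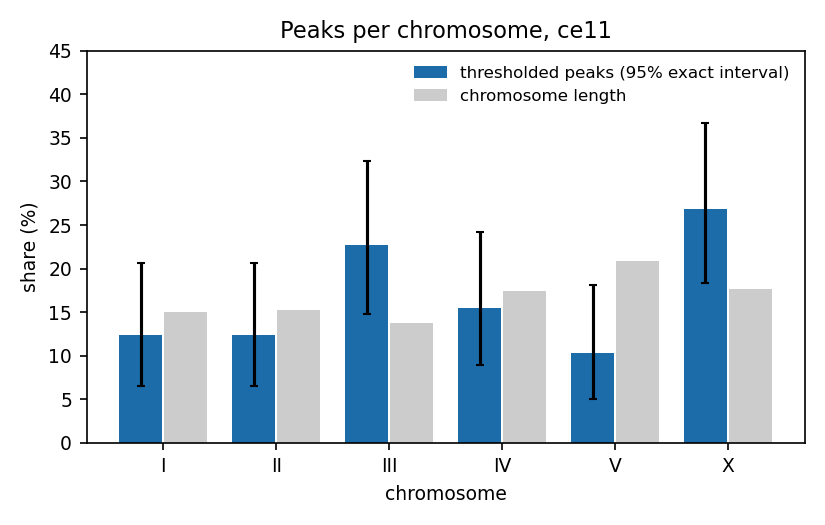
Share of the 97 thresholded ce11 peaks on each chromosome (blue bars, y axis in %, with exact 95% binomial intervals) beside the share of the nuclear genome's length (grey bars). Chromosome X held 26.8% of peaks and 17.7% of length, and chromosome V held 10.3% and 20.9%.

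The replicates shared a small core of strong regions. Of the 1000 strongest regions of replicate 1, 140 (14%, 11.9 to 16.3%) overlapped 1 of the 1000 strongest of replicate 2 by at least 1 bp. Random placement of replicate 2's regions on the same chromosomes gave a mean of 6.42 and at most 15 in 1000 placements (permutation p = 0.001, the smallest these can give). Among the 100 strongest of each, 23 overlapped, against a mean of 0.0590 at random (permutation p = 0.001). Of the 97 thresholded peaks, 90 overlapped the 1000 strongest regions of replicate 1, 78 those of replicate 2 and 73 both. This overlap is partly built in, since the peaks are the strongest regions of the list pooled from the same replicates. Across the 140 overlapping regions the signal values had a Pearson r of 0.446 and a Spearman rho of 0.329, which describes regions and not independent samples. Across the 96 thresholded peaks with a region in both replicates, selected on pooled signal, r was 0.0388 and rho -0.0816.

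The 7 peaks at ribosomal protein genes ranked from 1 to 28 in replicate 1 and from 3 to 780 in replicate 2. The peak at *rpl-3* ranked 1 and 10, that at *rpl-20* 4 and 3, that at *rpl-12* 16 and 155, and that at *rps-19* 28 and 780. The peak at *iff-2* ranked 2 and 1549, that at *cox-5A* 7 and 1269, that at *hsp-1* 5 and 2385, and that at *hsp-60* 40 and 27401; the contrast with the ribosomal protein peaks was not tested. A peak on chromosome X at 16929635 to 16930024, 5894 bp from the start of *C30E1.4* and singled out after its values were seen, ranked 7633 in replicate 1 and 1 in replicate 2. Among the 97 strongest regions of each replicate's own list, 57.7% of those of replicate 1 and 43.3% of those of replicate 2 were in promoter windows, a difference that did not pass a two-sided Fisher's exact test (p = 0.0617).

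The *skn-1* gene itself (WBGene00004804, chromosome IV, 5651039 to 5660384, minus strand) had no pooled region in the window of its outermost start. Within 20000 bp of its midpoint the pooled list held 16 regions, against a median of 12 over 10006 windows of the same size, a percentile of 81.7. The strongest of them, inside the gene at 5656892 to 5657281, ranked 195 with a signal of 24.9. Around *unc-119* (chromosome III, 10902641 to 10908935) the list held 6 regions, a percentile of 9.60, and replicate 1 had a region at rank 268 there. These percentiles are descriptive. The transgene adds a tagged copy of *skn-1*, so its copy number could raise signal at this gene. Such an effect and binding of SKN-1 there cannot be told apart here. That of *skn-1* was 97.8 within 10000 bp and 46.4 within 40000 bp, and that of *unc-119* 41.1 and 31.0 at these distances and 20.2 without replicate 1. On the ce10 assembly the authors' thresholded list held 110 peaks, which were counted and not placed on ce11.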

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

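Alternatives that use every annotated transcript start, or 1 gene per peak, were added after the data had been seen. Over all results, 66 of 84 alternatives kept the direction and the side of the threshold, or stayed within the spread allowed. The promoter share was higher than background in all 8 alternatives. The site share was higher than its background in 0 of 8 (the reversed control motif had 4.12% against 5.67%). Detoxification genes stayed at 0 in all 8. At most 0.526 genes were expected in these, so the counts of 0 do not show stability. The 66 include these 8 settings and the control motif. The ribosomal protein list passed in all 10, with 5 genes under 1 gene per peak against 7 in the main setting. The peaks found in both replicates stayed within 1.5 times the main count in all 5 alternatives; 78 and 90 were found in replicate 2 and replicate 1 taken alone. The overlap of the replicates was 85 for the 500 strongest regions, 645 for the 5000 strongest and 92 for summits within 100 bp, each above chance by permutation; the first 2 follow from the number of regions compared. The number of lists passing was 4 with 2000 bp upstream, 4 with the 500 strongest pooled regions shared with both replicates, 4 with all 825 of these (fewer than the 1000 planned), and 1 to 3 with a replicate left out. Adjusted p by Fisher's exact test, where under 0.05, was 0.000316 to 0.0300 for lysosome and autophagy (5 of 10 alternatives), 1.28e-05 to 0.0150 for chaperones (3 of 10) and 0.000112 to 0.0255 for depletion of chemoreceptors (4 of 10). The respiratory chain list had 0 to 3 genes with a replicate left out, and did not pass with the 500 strongest shared regions (3 genes, Fisher's exact test, adjusted p = 0.0947) or all of them (3 genes, adjusted p = 0.147 by the exact test). The X share was 25% in the 48 strongest peaks (exact binomial p = 0.186), where fewer peaks were tested, and passed unadjusted in the other 5 alternatives; adjusted over 6 chromosomes by the exact test, it passed in 2 of 6 (adjusted p from 0.0215 to 0.371). The percentile of regions around *skn-1* was 97.8 within 10000 bp, 46.4 within 40000 bp, 94.3 by summed signal, and 80.8 to 87.5 with a replicate left out; that around *unc-119* was 41.1 and 31.0 within those distances and 12.5 to 20.2 with a replicate left out. The cause was not tested except where stated. Unknown read depth limits all comparisons of the replicates' lists.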

Other observations

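The tests of short noncoding RNA genes, of hexamers, of the upper limit on the SKN-1 site and of gene lists between replicates, against other genes included, were chosen after the values they measure had been seen. The tests with GC-matched genes, simulated windows, GA runs, promoter-located regions and the gap between lists were written down before their results were seen. GAGAGA itself had by then been picked from the same summit windows.

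Genes for short noncoding RNAs, which belong to no fixed list, lay near many strong regions. Of the 1000 strongest pooled regions, 74 had their summit within 300 bp of a tRNA, snRNA, snoRNA or rRNA gene (7.40%, 5.85 to 9.20%), against 173 of the 14884 weakest (1.16%, 0.996 to 1.35%; two-sided Fisher's exact p = 5.52e-31). Transfer RNA genes were near 3.60% against 0.625% (Fisher's exact test, adjusted p = 2.54e-14), snoRNA genes near 3.20% against 0.396% (exact test, adjusted p = 7.03e-16), snRNA genes near 0.700% against 0.141% (exact test, adjusted p = 0.00169), and rRNA genes near 0 in both. Among the 97 peaks 6 lay near such genes. Those at ranks 29 and 42, with signals of 41.0 and 37.0, were next to *sls-2.3* and *sls-2.1*, which encode spliced leader RNAs used in trans-splicing of operon transcripts. The other 4 were next to the snoRNA genes *M7.15*, *D2021.6* and *W06H8.17* and a tRNA gene. Each of the peaks next to snoRNA genes also lay in the window of a protein-coding gene. That next to *D2021.6* was the peak counted at *sdha-1*, so these peaks are not separate from those at protein-coding promoters. The files do not state how reads from repeated tRNA genes were placed.

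The sequence around the summits had a marked composition. Of 2078 hexamers compared between the 97 summit windows and 194 flanking windows, 122 were more frequent and 52 less frequent at the summits after adjustment. This comparison was not corrected for base composition and did not pair peaks with their own flanks. GAGAGA led, in 50 peaks (51.5%, 41.2 to 61.8%) against 21 flanks (10.8%, 6.83 to 16.1%; Fisher's exact test, adjusted p = 3.90e-10). CGTCTC was in 43.3% against 10.3% (exact test, adjusted p = 3.88e-07) and CACGCG in 23.7% against 1.55% (exact test, adjusted p = 6.51e-07), while AAATTA was in 14.4% against 42.3% (exact test, adjusted p = 0.000207). GAGAGA fell to 11.5% in ranks 20001 to 29768 of the pooled list. Mean GC content fell from 46.5% (SD 6.57 over 97 regions) to 37.0% (SD 7.07 over 9768 regions) over the same ranks.

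Ribosomal protein promoters led the list although the SKN-1 site did not mark the peaks. The upper limit of the share of peaks with the site was 11.6%, which argues against direct binding through that site within 100 bp of the summit at most peaks. GC content of the promoter alone is argued against. Of 81 ribosomal protein genes, 14 had 1 of the 1000 strongest pooled regions. That is 4.39 times the mean of 10000 sets of genes matched on promoter GC (permutation p = 0.0001, the smallest these can give). The median promoter GC of the list was 38.5%. GC content near the summits, 46.5% on average in the 97 peaks, was not matched, so its effect stays open. The excess of regions near short noncoding RNA genes, 6.37 times the share in the weakest regions, is consistent with signal that may follow strong transcription or open chromatin in general rather than a SKN-1 site. That stays a hypothesis, since no mock-precipitated worms, expression values or other factors were analysed here, and no biological explanation other than the site was tested. The comparison near noncoding RNA genes was also not matched on GC content, and some of those regions lay at protein-coding promoters. Not every gene list had an excess. Among the 1000 strongest pooled regions, collagens had 3 genes against 4.34 expected and mitochondrial ribosomal proteins 1 against 1.64. The proteasome had 1 against 0.768 and tRNA synthetases 0 against 0.793. Chaperones had 10 against 1.49, lysosome and autophagy 5 against 0.818 and the respiratory chain 5 against 0.991. How strongly each list is transcribed in these worms was not measured, so these counts do not decide.

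The simple sequence effects tested did not account for GAGAGA at the summits, a hexamer picked from these same windows. Windows drawn from each summit window's own dinucleotides held it in at most 30 of 97 over 1000 sets, against 50 observed. Runs of GA of at least 20 bp, where reads may be misplaced, were in 0% of the windows with GAGAGA. Promoter location alone is argued against for these peaks. Promoter-located peaks had GAGAGA 4.19 times as often as promoter-located regions among the weakest (53.8% against 12.9%, Fisher's exact p = 3.28e-12). Peaks elsewhere had it in 48.9%. GAGAGA was picked as the leading one of 2078 hexamers in these windows. Neither the simulated windows nor the promoter comparison allows for that choice, so both contrasts may be too large. The promoter comparison was not matched on GC content. Which protein, if any, recognises the sequence in these worms stays open, and no biological explanation was tested.

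More chaperone genes had a strong region in replicate 1 than in replicate 2, a difference that did not pass after adjustment. In the 1000 strongest regions of each list, 12 chaperone genes had a region in replicate 1 and 4 in replicate 2, all 4 of them shared (exact McNemar p = 0.00781, adjusted p = 0.211 over 27 lists), while ribosomal protein genes numbered 16 and 11 (exact McNemar p = 0.267). A general weakness of replicate 2 at promoters may underlie both: over all protein-coding genes the numbers were 496 and 396, a factor of 1.25, and the gap between the lists' factors of 3 and 1.45 gave a permutation p of 0.133. Against all other genes found in 1 replicate alone (382 and 290), the chaperones (8 and 0) gave Fisher's exact p = 0.0124, but adjusted p = 0.334 over 27 lists. With 1 replicate of each and unknown depth, a general weakness and a chaperone-specific difference between the cultures cannot be told apart.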
